A study of Mus musculus with 12 samples.

How the data were processed

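RNA was measured in 12 libraries from mouse. The 6 cultured libraries come from germline stem cells (GSCs), 2 WT, 2 of Stag3 knockout line 1 (KO1) and 2 of line 2 (KO2). The 6 in vivo libraries come from testis germ cells, 2 each at embryonic days 16 and 17 (E16, E17) and at postnatal day 7 (P7). Per the labels, total RNA was extracted with a column kit and 1 ng was reverse transcribed and amplified, and sequencing libraries were made from the amplified cDNA. The design text calls the assay SC3-seq. Which cells were sorted, how GSCs were cultured and how the knockouts were made are not given in the sources used here.

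Per the submitters' processing notes, cutadapt 1.18, TopHat2 2.1.1, HTSeq 0.9.1 and Salmon 1.4.0 were used with genome build GRCm38.p6. The role of each tool and the strand setting are not given in the sources used here. The authors deposited a table without a header for each library. One of its columns holds whole read counts per gene, the deposited counts, and these were used for every test. Another deposited column holds values that the authors scaled from the counts to reads per 1000000 reads (RPM), with a total that leaves out spike-in, transgene and mitochondrial rows. It was checked against the counts and not used in tests. RPM given here were computed from the counts with the same total. Replicates were not pooled.

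The GSC, E16 and E17 tables share a list of 35652 genes, and the P7 tables use another list of 34896 genes, with 31675 genes in both by Entrez ID. In the GSC, E16 and E17 libraries the shared genes held 88.7% to 91.1% of gene counts, and in the P7 libraries 99.7%. Nearly all of the rest in the GSC, E16 and E17 libraries was mitochondrial genes, which held 8.82% to 10.96% of gene counts there. Symbols, positions and overlaps came from the RefSeq gene table for the same build, in which 35574 of the 35652 IDs and 32466 of the 34896 IDs were found. For GSC WT the replicate numbers in the titles and in the file names are opposite, and the titles were used. Blank count cells of genes were treated as missing and those genes were left out of fits that need them. The mitochondrial genes are blank at P7, so no mitochondrial level at P7 is given. Blank cells of spike-in and transgene rows were read as 0.

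Each table also holds 92 ERCC spike-in rows, 4 other spike-in rows and 5 transgene rows, which were left out of the gene tests. Total counts per library ranged from 1938644 to 4596607, and the value of each is given with the results. A floor of 3 counts per library, averaged over the group, gave the lower bound of a fold against a group at 0. Where a group had 1 to 3 counts, the ratio was given with its exact 95% counting interval. Both cover counting error only, and molecular identifiers are not given in the sources used here.

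Comparisons were made with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr by group, no robust option), with a Benjamini-Hochberg adjusted p threshold of 0.05. One fit held the 6 GSC libraries with a coefficient per group and gave the mean of both knockout lines against WT, KO1 against WT, KO2 against WT and KO1 against KO2. A fit of the 6 in vivo libraries over the shared genes gave E17 against E16 and P7 against E17. A fit of all 12 libraries over the shared genes gave P7 against GSC WT. The comparisons, the tests, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined.

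Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and with Benjamini-Hochberg adjustment over the lists of a comparison. The test was repeated with a correlation estimated from the data, and with fry, which asks whether the genes of a list move on balance in 1 direction. Counts of changed members were also adjusted over the list alone. The 29 lists were cohesin, condensin, undifferentiated and differentiating spermatogonia, GDNF and FGF response, retinoic acid response, meiotic prophase, piRNA pathway, DNA methylation, fetal male germ cell, pluripotency, cell cycle, p53 targets, interferon response, imprinted genes, the protocadherin beta, Hox and Rhox clusters, ribosomal protein, mitochondrial, oxidative phosphorylation and glycolysis genes, and markers of Sertoli, Leydig, peritubular myoid, endothelial, macrophage, fibroblast and feeder, and erythroid cells. Stag3 was left out of the cohesin list in the knockout comparisons. Lists with fewer than 3 tested members were given only as sums, which left 24 lists in the GSC fit and 26 in vivo. The pattern first written for mitochondrial genes matched no symbol, so the 13 mitochondrially encoded genes were listed by name.

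Named genes were the 10 with the largest rise and the 10 with the largest fall among genes past the threshold whose libraries did not overlap between the sides and whose mean in the higher group was at least 20 RPM. Symbols of the form Gm with a number, names ending in Rik, mitochondrial genes and ribosomal protein genes were excluded. Stag3, the cohesin genes and up to 4 members of each list were added, those past the threshold with the lowest adjusted p or, where none passed, the most highly expressed. Genes named outside this rule are said to have been chosen after their values were seen.

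The overlap of the knockout lines was compared with n1 x n2 / N per direction. The correlation and covariance of their fold changes were compared with 50 simulations of unchanged lines. In these, all libraries, WT included, were drawn from a model with the WT level and the fitted spread of each gene. Both simulated lines shared the drawn WT libraries. The pipeline was tested on simulated data in which the mean levels of 200 genes were changed. All counts were drawn from a model with the level and spread fitted to each gene, so spread that the model misses is not covered. In the mean of both knockout lines 50.7% of genes changed 1.5-fold, 74.6% changed 2-fold and 95.5% changed 4-fold were called, with 7 of 11690 unchanged genes called. The shares were 7.5%, 43.3% and 74.2% for E17 against E16 and 14.9%, 53.7% and 66.7% for P7 against GSC WT.

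Alternatives were another scaling (DESeq2 1.42.0 size factors), another test (DESeq2 Wald), no filter and a stricter filter on low counts (at least 20 RPM in at least 2 libraries), an added log2 threshold of 1, all 12 libraries in a single fit or, for P7 against GSC WT, those groups alone, both knockout lines as 1 group, replicate number as a block, and each library left out in turn. ERCC totals as size factors, the fit without mitochondrial genes, the fit without 16804 genes that overlap another gene and the fit without 37 genes near 0 with 1 of the gene lists were added after the data were seen. Groups of 2 are too small for a test of single outlying libraries or for a count of other splits. Tables were handled with R 4.3.3, data.table (1.17.8), python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.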

Results

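Gene expression was measured by SC3-seq, a method that sequences the 3' ends of amplified cDNA, in 12 mouse libraries of the male germline. The libraries formed 6 groups of 2. Cultured germline stem cells (GSCs), which are spermatogonial stem cells kept in culture, came from the line Acrosin-EGFP; beta-Actin-EGFP and were wild type (WT) or belonged to 1 of 2 Stag3 knockout lines, named KO1 and KO2. Germ cells of the testis came from mice that carried a Vasa-RFP transgene, at embryonic day 16 (E16), embryonic day 17 (E17) and postnatal day 7 (P7). The series was designed to characterise STAG3-cohesin in cultured cells and in germ cells in vivo, and female germ cells were not analysed here.

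Total counts were 4159038 and 4596607 in the WT libraries, 3887863 and 3312252 in KO1, and 4232035 and 4149814 in KO2. The E16 libraries held 2267245 and 3198503 counts, the E17 libraries 1938644 and 2151227, and the P7 libraries 3230225 and 3394753. A count of 0 allowed a level of up to 0.75 to 1.05 RPM in a GSC library, up to 1.06 to 1.73 in a fetal library and up to 0.93 to 0.99 in a P7 library. These floors and all intervals given below cover counting error only. Levels are reads per 1000000 reads of non-mitochondrial genes (RPM), given as means of 2 libraries with their SD, and log2 fold changes carry the standard error (SE) of the fit. The labels do not say whether replicates are separate cultures or animals, so p-values measure only the spread between these samples. The strand setting of the counting is not stated, so values of overlapping or antisense genes and of close paralogs are uncertain.

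Stag3, which encodes a cohesin subunit best known from meiosis, was read first in every library. The gene lies on chromosome 5 from 138272514 to 138312397 (GRCm38.p6, Entrez ID 50878), and the annotation places Gal3st4 and Gpc2 over parts of it. Its level in GSCs was 403 ± 25.2 RPM in WT (SD, n = 2), 299.5 ± 7 in KO1 and 145 ± 10.5 in KO2. In vivo it was 438 ± 37.4 at E16, 525 ± 14.3 at E17 and 229.8 ± 4.13 at P7. Stag3 RNA was thus still counted in both knockout lines, and a 3' tag that lies outside the altered part of a gene does not check the knockout. Against WT the log2 fold change was -0.48 ± 0.08 in KO1 (adjusted p = 1.21e-05, edgeR quasi-likelihood test, Benjamini-Hochberg) and -1.52 ± 0.09 in KO2 (adjusted p = 6e-28). KO1 stood above KO2 by 1.05 ± 0.09 (adjusted p = 3.26e-16). Stag3 did not pass the test between E17 and E16 (log2 fold change -0.08, adjusted p = 0.754). Its direction there depends on the scaling, since the RPM means run the other way, and the fold change was 0.08 without E16 replicate 2. Stag3 fell from E17 to P7 (-1.03 ± 0.13, adjusted p = 5.05e-06) and was lower at P7 than in WT GSCs (-0.94 ± 0.11, adjusted p = 9.41e-09).

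**Figure D1:**
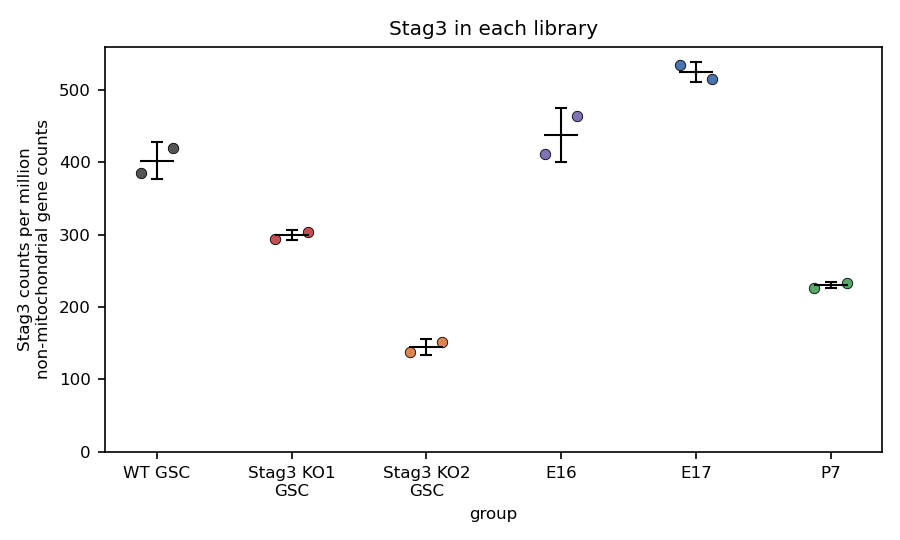
Stag3 level in RPM (linear vertical axis from 0) in each of the 6 groups, with points for single libraries and bars for the group mean ± SD (n = 2). The KO1 libraries average 299.5 and the KO2 libraries 145, both below the WT mean of 403, and the P7 mean of 229.8 lies below the E17 mean of 525.

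The first comparison asked which genes differ between Stag3 knockout and WT GSCs, taking the mean of both lines. Several regulators of spermatogonia fell steeply. Tex19.1, a germ cell factor that restrains retrotransposons, dropped from 39.4 ± 3.79 RPM in WT to 3.95 ± 0.65 in KO1 and 0.14 ± 0.19 in KO2. Sohlh1, a transcription factor of spermatogonial differentiation, dropped from 58.9 ± 10.7 to 6.43 ± 0.78 and 1.22 ± 1.33 (log2 fold change -4.42 ± 0.24). Sox3, a transcription factor expressed in spermatogonia, went from 81.6 ± 12.8 to 11.7 ± 2.2 and 10.9 ± 3.27 (-2.89 ± 0.16). In the other direction, the neurofilament gene Nefm rose from 59.0 ± 2.04 to 241 ± 25.3 and 263 ± 13.5 (2.05 ± 0.1), and the AKT co-activator Tcl1 rose from 21.2 ± 0.41 to 90.1 ± 0.48 and 92.7 ± 5.07 (2.06 ± 0.14). Adjusted p-values (edgeR quasi-likelihood test, Benjamini-Hochberg) were 1.36e-27 for Tex19.1, 1.09e-30 for Sohlh1, 2.55e-29 for Sox3, 5.35e-34 for Nefm and 6.74e-23 for Tcl1.

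The other genes with the largest rises were the ephrin receptor Epha2 (log2 fold change 2.44), the receptor Gpr83 (2.29), the adhesion gene Mpzl2 (2.24), Tmem132e (2.16), the adhesion receptor Adgrl2 (2.05), the AP-1 gene Junb (2.02), the transcription factor Foxa2 (1.98) and Rap1gap2 (1.92). The largest falls also included the meiotic recombination gene Hsf2bp (-3.29), Rin2 (-2.87), the interferon-inducible Ifi27 (-2.51), the transcription factors Atoh8 (-2.37) and Foxf1 (-1.995), Pxt1 (-1.89) and the centrosome gene Sfi1 (-1.73). By the rule that chose these 20 genes, all 4 knockout libraries lie on the same side of both WT libraries for each. Nefm, Rin2, Ifi27, Atoh8, Pxt1 and Sfi1, 6 of the 20, overlap another annotated gene.

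Of 13 genes that respond to GDNF and FGF, the growth factors that sustain spermatogonial stem cells, 9 rose and 3 fell, or 10 and 3 adjusted over the list alone. Etv5, a transcription factor needed for stem cell self-renewal, rose from 57.2 ± 6.16 RPM to 170.3 ± 17.2 in KO1 and 193 ± 2.87 in KO2 (log2 fold change 1.62 ± 0.1, adjusted p = 4.84e-25, edgeR quasi-likelihood test, Benjamini-Hochberg). The ERK phosphatase gene Dusp6 (1.91 ± 0.13), the feedback inhibitor gene Spry4 (3.78 ± 0.49) and Etv4 (1.70 ± 0.18) rose as well. The 3 members that fell, named after their values were seen, were Mycn (-0.66), a proto-oncogene, Id4 (-0.57), which marks the stem cell state, and the early response gene Egr1 (-0.35). Of 22 genes of the piRNA pathway, which silences transposons in germ cells, 0 rose and 16 fell, the same counts as adjusted over the list alone. Piwil2, a PIWI protein, went from 255 ± 0.72 to 181 ± 11.2 and 144 ± 2.56 (-0.71 ± 0.08), and Fkbp6 (-0.60 ± 0.09) and Tdrd1 (-0.57 ± 0.09) fell by similar amounts. The helicase gene Tdrd9 had 62 counts in WT against 1 in the 4 knockout libraries, a ratio of levels of 109.5 (95% counting interval 18.9 to 4393).

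The camera test (preset correlation 0.01, Benjamini-Hochberg over the lists) placed the GDNF and FGF list above other genes (adjusted p = 7.95e-13, median log2 fold change 1.00) and the piRNA list below them (adjusted p = 2.68e-11, median -0.43). Both had adjusted p = 0.0684 with an estimated correlation. Of 9 genes of differentiating spermatogonia, 1 rose and 5 fell (2 and 5 adjusted over the list alone), with Sohlh1, the receptor gene Kit (-1.70 ± 0.17) and Crabp1 (-0.94 ± 0.11) lower and the cyclin gene Ccnd2 (0.56 ± 0.08) higher. This list had a camera adjusted p of 2.11e-05, and adjusted p = 0.202 with an estimated correlation. Kit stood at 62.1 ± 28.1 RPM in WT, so the size of its fall rests on 2 WT libraries that differed widely. Of 26 genes of undifferentiated spermatogonia 6 rose and 11 fell (8 and 12 adjusted over the list alone), and the list as a whole did not pass (camera adjusted p = 0.0926). Sox3 and the early response gene Egr4 (-1.40 ± 0.09) fell while Etv5 and Tcl1 rose.

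**Figure D2:**
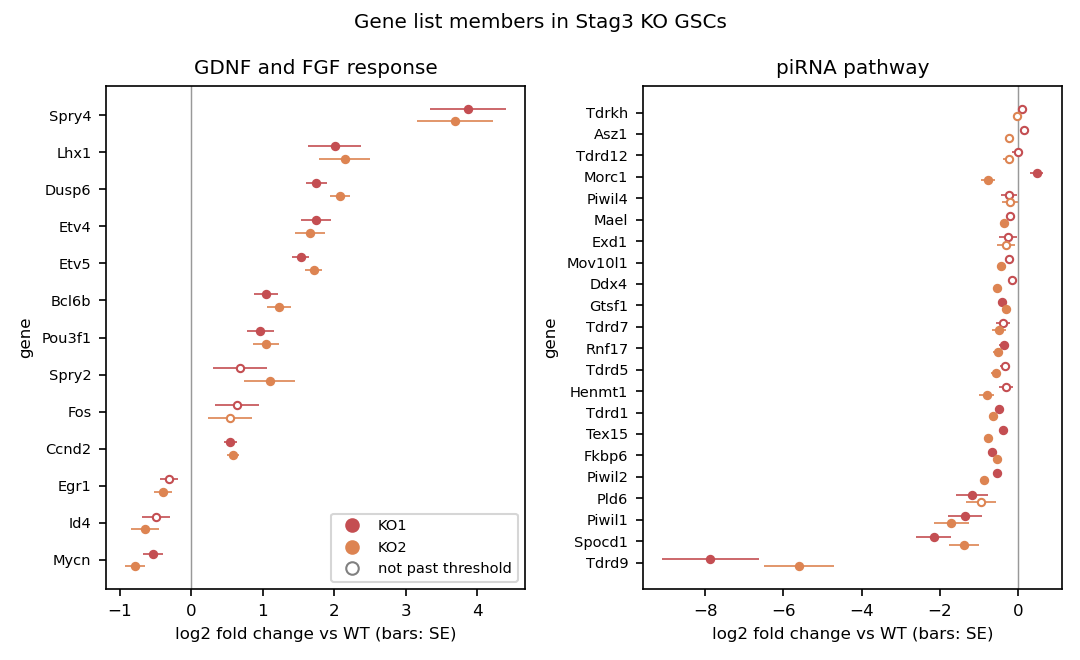
Log2 fold change against WT (horizontal axis, point ± SE) of each tested member of the GDNF and FGF response list and of the piRNA pathway list. KO1 and KO2 have separate points, filled for genes past the adjusted threshold in that line and open for the rest. Of the filled KO1 points, 8 lie to the right and 1 to the left in the first list, and 1 and 10 in the second. Of the filled KO2 points, 9 lie to the right and 3 to the left in the first list, and 0 and 16 in the second.

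Of 8 condensin genes, which compact mitotic chromosomes, 4 rose and 0 fell by either adjustment, with Smc4 at 0.56 ± 0.07 and Ncapg at 0.44 ± 0.09 (camera adjusted p = 0.00153, and adjusted p = 0.202 with an estimated correlation). Of 24 cell cycle genes 9 rose and 1 fell (10 and 1 adjusted over the list alone), with Mki67 at 0.69 ± 0.09 and Cdk1 at 0.55 ± 0.09 (camera adjusted p = 0.00844, and adjusted p = 0.21 with an estimated correlation). Of 20 cohesin genes other than Stag3, 4 rose and 0 fell by either adjustment, namely Smc1b (0.31 ± 0.07), Pds5a (0.31 ± 0.1), Smc1a (0.34 ± 0.12) and Sgo2a (0.42 ± 0.15), and the list did not pass (camera adjusted p = 0.238). The paralog Stag1 stood at 176, 166 and 167 RPM in WT, KO1 and KO2, and Rec8 at 98.2, 103 and 95.4, neither past the threshold. With ERCC spike-in totals as size factors 0 cohesin genes passed (edgeR quasi-likelihood test, 4 at an unadjusted p under 0.05), 3 condensin genes rose, and 4 cell cycle genes rose and 0 fell. In KO1 alone 1 cell cycle gene rose and 1 fell with these totals, against 6 and 1 without them, and 1 condensin gene rose against 4. With these totals the KO1 medians of the cohesin list (0.04 to -0.06), the cell cycle list (0.07 to -0.03) and the p53 target list (0.09 to -0.02) changed sign.

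Other lists passed the camera test through small changes or few members. Of 79 ribosomal protein genes 3 rose and 32 fell (4 and 43 adjusted over the list alone), with a median log2 fold change of -0.14, examples Rpl39l (-0.48) and Rpl13a (-0.36), and Rps4x (0.52) going the other way. Their camera adjusted p was 1.12e-05, and adjusted p = 0.54 with an estimated correlation. With ERCC totals 1 of them rose and 6 fell, and the number that fell went from 28 to 13 in KO1 and from 21 to 1 in KO2. Of 13 mitochondrially encoded genes 6 rose and 1 fell (7 and 1 adjusted over the list alone), with COX1 at 0.80 ± 0.05 and COX3 at -0.24 ± 0.05 (camera adjusted p = 0.00366, and adjusted p = 0.5 with an estimated correlation), and 3 rose and 0 fell with ERCC totals. Of 7 interferon response genes 1, Oasl2 (-0.83 ± 0.12), fell and 0 rose by either adjustment (camera adjusted p = 0.0321, and adjusted p = 0.279 with an estimated correlation). The median log2 fold change of these 7 was -0.715, with 6 of them not past the threshold. None of the 9 calls at the preset correlation was kept with an estimated one.

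Of 9 fibroblast and feeder genes 0 rose and 5 fell by either adjustment, among them the collagens Col3a1 (-1.70 ± 0.21) and Col1a2 (-1.71 ± 0.27), with a camera adjusted p of 0.00999 and adjusted p = 0.221 with an estimated correlation. The summed level of the 12 listed genes was 281 ± 0.99 RPM in WT, 256 ± 5.81 in KO1 and 247 ± 2.81 in KO2. Of 5 Sertoli cell genes Aard (1.38 ± 0.23) and Clu (1.93 ± 0.51) rose and Wt1 (-0.80 ± 0.28) fell, 3 and 1 adjusted over the list alone (camera adjusted p = 0.145). The sum over all 13 listed Sertoli genes, tested or not, was 36.1 ± 2.53 RPM in WT, 64.6 ± 1.47 in KO1 and 47.4 ± 3.62 in KO2. Of 3 endothelial genes 0 rose and 0 fell (camera adjusted p = 0.508). The macrophage and protocadherin beta lists were too low to test, with sums of 1.95 and 0 RPM in WT.

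The remaining lists did not pass the camera test. Of 33 meiotic prophase genes 2 rose and 3 fell (1 and 3 adjusted over the list alone), with Tex12 (-1.28 ± 0.15) and Sycp3 (-0.53 ± 0.08) lower and Meioc (0.59 ± 0.13) higher (adjusted p = 0.944). Tex12 stood at 78 ± 35.2 RPM in WT, so its 2 WT libraries differed widely too. Of 12 pluripotency genes 1 rose and 4 fell (3 and 4 adjusted over the list alone), with Pou5f1 at -3.46 ± 0.66 and Dppa4 at 0.71 ± 0.15 (adjusted p = 0.432). Of 7 fetal male germ cell genes Elavl2 (0.68) rose and Nanos3 (-1.27) and Dnd1 (-0.36) fell, 1 and 3 adjusted over the list alone (adjusted p = 0.187). Of 16 imprinted genes 1 rose and 3 fell by either adjustment, with H19 at -1.55 ± 0.17 and Slc38a4 at 0.83 ± 0.14 (adjusted p = 0.238). Of 11 p53 targets 3 rose and 0 fell (4 and 1 adjusted over the list alone), with Pmaip1 at 0.73 and Ccng1 at 0.35 (adjusted p = 0.0867). Of 10 Hox genes Hoxb9 (0.91) and Hoxb5 (0.92) rose, and of 7 Rhox genes Rhox10 (-0.86) and Rhox7a (-0.50) fell, each by either adjustment (adjusted p = 0.238 and 0.441). Of 15 glycolysis genes 1 rose and 4 fell (1 and 7 adjusted over the list alone), with Slc2a1 at -1.09 and Ldha at 0.50 (adjusted p = 0.218).

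Of 90 oxidative phosphorylation genes 10 rose and 8 fell by either adjustment, with Ndufv3 at -0.68 and Atp5pb at 0.36 (camera adjusted p = 0.803), and 2 rose and 1 fell with ERCC totals. Of 6 DNA methylation genes Uhrf1 (0.29) rose and Dnmt3b (-0.63) fell, 2 and 1 adjusted over the list alone (adjusted p = 0.763). Of 5 retinoic acid response genes Stra8 (-0.29) fell and 0 rose by either adjustment (adjusted p = 0.906). The mean and the median differed in sign for the retinoic acid list (0.05 and -0.04), the meiotic list (0.05 and -0.01) and the Rhox list (-0.15 and 0.20), and camera placed all 3 lower.

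Across all 11890 genes tested, 2286 passed the threshold, 1027 higher and 1259 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The share of changed genes that were higher was 44.9% here and 31.5% when all 12 libraries shared a fit. The count was 1421 in that shared fit, 1083 by DESeq2, 1447 with ERCC totals as size factors and 566 with an added log2 threshold of 1.

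Each line was then set against WT on its own, which asks whether the change was seen in both. KO1 shared with KO2 the low Sohlh1, Sox3, Hsf2bp and Rin2 and the high Epha2, Nefm, Tcl1, Mpzl2, Tmem132e, Adgrl2 and Junb described above. In KO1 the list for size of change added the cancer-testis antigen gene Magea8 (log2 fold change 2.097 ± 0.19, from 16.004 ± 4.15 to 71.4 ± 2.28 RPM) and Smad3, which carries TGF-beta signals (-1.68 ± 0.3). In KO2 it added Itpkb (2.13), Dusp6 (2.08), the transketolase-like gene Tktl1 (from 85.2 ± 10.5 to 0.69 ± 0.21), Kit (-2.32 ± 0.21), the imprinted H19 (-2.24 ± 0.22) and Col3a1 (-2.04 ± 0.26). Tex19.1 fell by 3.35 ± 0.31 on the log2 scale in KO1, and in KO2 it had 1 count against 304 in WT, a ratio of 289.1 (95% counting interval 51.5 to 11450). Tdrd9 had 0 counts in KO1, at least 8.34-fold lower than in WT with a floor of 3 counts per library.

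The 2 list calls with the lowest p-values in the mean of both lines were seen in each line. In KO1 the ribosomal protein list (camera adjusted p = 3.44e-08) ranked ahead of the piRNA list. In KO1, 8 GDNF and FGF genes rose and 1 fell (9 and 3 adjusted over the list alone, camera adjusted p = 1.13e-12), while 1 piRNA gene (Morc1, named after its value was seen) rose and 10 fell (1 and 13 adjusted over the list alone, camera adjusted p = 1.69e-06). Both lists had adjusted p = 0.128 with an estimated correlation. In KO2, 9 GDNF and FGF genes rose and 3 fell by either adjustment (camera adjusted p = 3.3e-13), and 0 piRNA genes rose and 16 fell (0 and 18 adjusted over the list alone, camera adjusted p = 5.9e-14). Both had adjusted p = 0.0649 with an estimated correlation. In KO1 Aard, Clu and Sox9 of the Sertoli list rose and 0 fell by either adjustment (camera adjusted p = 0.0248, and adjusted p = 0.265 with an estimated correlation). In KO2 Ccng1, Pmaip1 and Zmat3 of the p53 targets rose by either adjustment and 0 fell (camera adjusted p = 0.012, and adjusted p = 0.207 with an estimated correlation). Camera called 11 of 24 lists in KO1 and 9 in KO2, and 0 with an estimated correlation in either line. In both lines the condensin, differentiating spermatogonia, cell cycle, ribosomal protein, mitochondrial and fibroblast lists were called, with adjusted p = 0.183 to adjusted p = 0.645 with an estimated correlation. KO1 added the interferon list (adjusted p = 0.265 with an estimated correlation) and glycolysis, where 0 rose and 5 fell (1 and 6 adjusted over the list alone, adjusted p = 0.434 with an estimated correlation).

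In KO1 1622 of 11890 genes changed, 742 higher and 880 lower, and in KO2 1860 changed, 855 higher and 1005 lower (edgeR quasi-likelihood test). Without KO1 replicate 1 or 2 the KO1 count was 875 and 859, and without KO2 replicate 1 or 2 the KO2 count was 977 and 905. The counts were 679 and 864 by DESeq2, 858 and 1008 with all 12 libraries in the fit, 514 and 564 with an added log2 threshold of 1, and 1191 in KO2 with ERCC totals. The share of changed genes that were higher was 45.7% in KO1 and 46% in KO2, against 25.9% and 58.4% with ERCC totals, which moved the median of all genes in KO1 by -0.10 on the log2 scale. With all 12 libraries in the fit the KO1 share was 30.4%.

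Both lines called 1035 genes in the same direction, 470 higher and 565 lower, and 6 in opposite directions. Independent calls would share 53.4 higher and 74.4 lower genes. Both comparisons use the same WT libraries. In 50 simulations, with the WT libraries drawn from the fitted model as well, an unchanged line had a mean of 0.06 calls. That is too few for a count of shared calls to compare with. The log2 fold changes of the 2 lines correlated at 0.766 across genes, which are not independent replicates, against a simulated mean of 0.483 and a highest value of 0.514. Their covariance was 0.312 against a simulated mean of 0.049 and a highest value of 0.054. The simulation gave WT the same spread as the knockout lines. Between the real replicates the chi-square of counts per degree of freedom was 3.35 in WT, 1.99 in KO1 and 1.85 in KO2. The simulated correlation and covariance may therefore be too low. Part of the overlap may still come from the shared WT libraries, since 2 libraries cannot be split into separate controls. The shared count was 612 and 655 without KO1 replicate 1 or 2, 643 and 605 without KO2 replicate 1 or 2, 545 with all 12 libraries in the fit, 461 by DESeq2, 595 with ERCC totals and 320 with an added log2 threshold of 1.

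**Figure D3:**
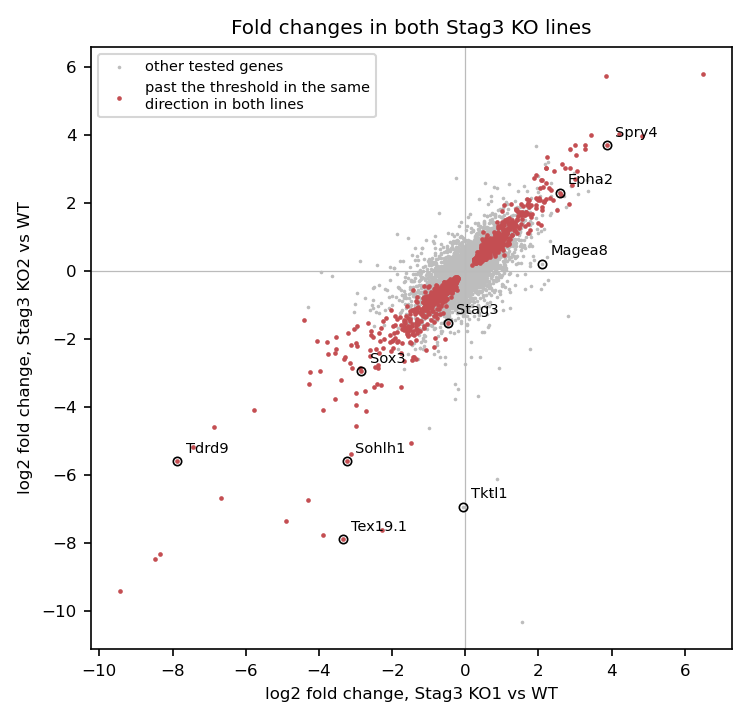
Log2 fold change against WT of each of 11890 genes in KO1 (horizontal axis) and KO2 (vertical axis), with red points for the 1035 genes past the threshold in the same direction in both lines. The values correlate at 0.766 across genes, and both axes share the WT libraries.

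The direct comparison of the lines asked where their effects differ. Tktl1 stood at 83.7 ± 0.16 RPM in KO1, against 85.2 ± 10.5 in WT, and at 0.69 ± 0.21 in KO2 (log2 fold change KO1 against KO2 6.86 ± 0.31, adjusted p = 7.22e-37, edgeR quasi-likelihood test, Benjamini-Hochberg). Other genes higher in KO1 were Kit (1.25 ± 0.23), the synaptonemal complex gene Tex12 (1.43 ± 0.2), Dmrtc2 (1.58 ± 0.22) and Morc1 (1.25 ± 0.17), which silences transposons. Magea8 (1.88), Magea5 (1.44), H19 (1.39) and the histone demethylase gene Kdm5c (1.16) were also higher in KO1, beside Stag3 itself. Higher in KO2 were Myof (-1.49 ± 0.29), the basement membrane gene Nid1 (-1.22 ± 0.16), Atp2b4 (-0.97), Ikbkb (-0.95), Gba2 (-0.89), Pou2f2 (-0.88), Afp (-0.86), Tctn2 (-0.86), LOC108167440 (-0.84) and Zfp704 (-0.79). Of the 15 alternatives tried, Kdm5c and Zfp704 kept their call in 7, Atp2b4 and Tctn2 in 8, Ikbkb, Pou2f2 and LOC108167440 in 9, Gba2 and Afp in 10, Myof in 13, Tex12 in 14 and the others in all 15. Of these 20 genes, 10 overlap another annotated gene, Stag3 among them.

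Of 9 differentiating spermatogonia genes, Kit, Stra8 (0.48 ± 0.1) and Sohlh1 (2.34 ± 0.5) were higher in KO1 and 0 lower, or 4 and 0 adjusted over the list alone (camera adjusted p = 5.39e-05). Of 33 meiotic genes 1 was higher (4 adjusted over the list alone) and 0 lower, and of 22 piRNA genes Morc1 and Ddx4 (0.38 ± 0.08) were higher (6 adjusted over the list alone) and 0 lower, each with a camera adjusted p of 3.21e-05. All 3 lists had adjusted p = 0.326 with an estimated correlation. With ERCC totals the piRNA median of 0.16 became -0.003, the meiotic median of 0.20 became 0.04 and the differentiating median of 0.35 became 0.18. Camera called 10 lists, 0 with an estimated correlation. The others were the retinoic acid and Sertoli lists, higher in KO1, and the p53, Hox, ribosomal protein, mitochondrial and glycolysis lists, lower, with adjusted p = 0.326 to adjusted p = 0.724 with an estimated correlation. At most 3 members of any of them passed in 1 direction. The mitochondrial list had a median of 0.02, a mean of -0.09 and a median of -0.14 with ERCC totals, and the retinoic acid median of 0.11 became -0.06.

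In total 99 genes differed between the lines, 65 higher in KO1 and 34 lower (edgeR quasi-likelihood test, with 1136 at an unadjusted p under 0.05). The count was 189 and 185 without WT replicate 1 or 2, 43 and 41 without KO1 replicate 1 or 2, 45 and 42 without KO2 replicate 1 or 2, 39 with all 12 libraries in the fit, 35 by DESeq2 and 50 with an added log2 threshold of 1. The share higher in KO1 was 65.7%, against 37% with ERCC totals, which moved the median of all genes by -0.16, and 82.1% with all 12 libraries in the fit.

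E17 was compared with E16 to follow consecutive fetal stages of male germ cells. Ribosomal protein genes were lower at E17 almost throughout. Of 80 tested, 0 rose and 75 fell (0 and 77 adjusted over the list alone), with a median log2 fold change of -0.88 and Rpl36a at -1.73 ± 0.13 and Rpl15 at -1.39 ± 0.11. Of 91 oxidative phosphorylation genes 0 rose and 38 fell (1 and 55 adjusted over the list alone). Cox7b, a subunit of cytochrome c oxidase, went from 363 ± 30.3 to 103 ± 3.74 RPM (-2.16 ± 0.15, adjusted p = 2.7e-06, edgeR quasi-likelihood test, Benjamini-Hochberg), and Ndufs4 of complex I from 403 ± 70.4 to 123 ± 0.32 (-2.06 ± 0.16). The camera adjusted p was 1.05e-110 for the ribosomal list and 1.86e-22 for the oxidative phosphorylation list, and adjusted p = 0.378 with an estimated correlation for both. In the 2 E16 libraries ribosomal protein genes took 20.6% and 23.4% of gene counts, and in the E17 libraries 14.6% and 14.7%. ERCC spike-ins took 1.37% of all counts at E16 and 0.213% at E17. ERCC totals were not tried as size factors here, so these falls are relative to the other genes.

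Of 23 piRNA genes 0 rose and 5 fell (0 and 9 adjusted over the list alone), among them Morc1 (-1.21 ± 0.13) and Piwil4 (-0.89 ± 0.12), the PIWI protein of fetal male germ cells. Of 11 fetal male germ cell genes 1 rose and 4 fell (2 and 4 adjusted over the list alone), with Dppa3 (-2.02 ± 0.36), a gene of early germ cells, Dnd1 (-0.81 ± 0.15) and Dnmt3l (-0.63 ± 0.13), a cofactor of de novo DNA methylation, lower and the RNA-binding Elavl2, named after its value was seen, higher. Of 16 pluripotency genes Utf1 (-1.02 ± 0.14), Dppa3 and Pou5f1 (-0.68 ± 0.18) fell and 0 rose by either adjustment. Camera adjusted p-values were 3.31e-05, 0.0178 and 0.0312 for these lists, each with adjusted p = 0.378 with an estimated correlation. Of 33 meiotic genes Spo11 (1.70 ± 0.3), which cuts DNA to start recombination, rose and 0 fell by either adjustment (camera adjusted p = 0.0909). Of 21 cohesin genes Pds5a (0.89) and Pds5b (0.87) rose and 0 fell by either adjustment (camera adjusted p = 0.633).

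Of 5 erythroid genes the globins Hba-a1 (-2.70 ± 0.62) and Hbb-bs (-2.17 ± 0.52) fell and 0 rose (0 and 3 adjusted over the list alone, camera adjusted p = 0.0312, and adjusted p = 0.618 with an estimated correlation). The summed level of all 7 listed erythroid genes was 207 ± 92.4 RPM at E16 and 101 ± 11.2 at E17. Of 11 fibroblast and feeder genes Col1a2 (1.12 ± 0.25) rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.0414, and adjusted p = 0.618 with an estimated correlation), and all 12 listed ones summed to 447 ± 26.8 and 674 ± 22. The Sertoli, Leydig, peritubular myoid and endothelial lists had 0 changed genes by either adjustment, and sums over all their listed genes were 178, 34.0, 90.9 and 131 at E16 against 209, 49.0, 110.7 and 165 at E17.

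The genes with the largest rises to E17 were the secretogranin gene Scg2 (from 3.64 ± 1.17 to 30.4 ± 4.46 RPM, log2 fold change 2.74 ± 0.46), the carbonic anhydrase Car4 (2.09), Plaur (1.997), Col24a1 (1.93), Tgm6 (1.92), the imprinted Sgce (1.90), Cd160 (1.87), Ell3 (1.87), D17H6S56E-5 (1.86) and Fam122b (1.80). Beside the globins, Cox7b, Ndufs4 and Dppa3, the largest falls were Abcc10 (-2.24), Svs4 (-2.05), Actn2 (-1.98), Hsd17b2 (-1.95) and Bloc1s5 (-1.90), and 4 of the 20 overlap another gene. Of the 13 alternatives tried, Plaur kept its call in 7, Fam122b in 9, Car4, Tgm6, Sgce and Svs4 in 10, Scg2 and both globins in 11, Ell3 in 12 and the others in all 13. In all 975 of 14776 genes changed, 242 higher and 733 lower, so that 24.8% were higher (edgeR quasi-likelihood test). The count was 3645 and 1506 without E16 replicate 1 or 2, with 45.1% and 34.1% higher, and 232 and 260 without E17 replicate 1 or 2, with 12.1% and 13.1% higher. It was 1763 with all 12 libraries in the fit and 335 with an added log2 threshold of 1. The E16 libraries correlated at 0.925 in log-scaled counts, the lowest of any replicate pair, and E16 replicate 1 correlated more closely with the E17 libraries (0.936 with each).

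P7 was compared with E17 to set postnatal against fetal germ cells. Zbtb16, a transcription factor of stem cell maintenance, rose from 4.4 ± 0.31 to 157 ± 15.9 RPM (log2 fold change 5.30 ± 0.28, adjusted p = 1.48e-09, edgeR quasi-likelihood test, Benjamini-Hochberg), and Gfra1, the GDNF receptor, rose by 3.63 ± 0.23 on the log2 scale. Dnmt3l fell from 772 ± 4.47 to 8.56 ± 1.88 (-6.32 ± 0.18, adjusted p = 4.22e-12). The cyclin gene Ccnd2 rose by 3.35 ± 0.19 on the log2 scale. The P7 libraries were counted with another gene list and carry library names that the others lack, so stage, gene list and library set cannot be told apart in this comparison. ERCC spike-ins took 0.213% of all counts at E17 and 5.27% at P7, and ERCC totals were not tried as size factors here either.

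Of 27 undifferentiated spermatogonia genes 16 rose and 5 fell (17 and 5 adjusted over the list alone, camera adjusted p = 3e-06), with Utf1 (-3.00 ± 0.17) among those that fell. Of 13 GDNF and FGF genes 10 rose and 0 fell (11 and 0 adjusted over the list alone, camera adjusted p = 3.45e-08), with Etv5 at 3.7996 ± 0.24 and Dusp6 at 5.91 ± 0.42. Both had adjusted p = 0.138 with an estimated correlation. Of 24 cell cycle genes 23 rose and 0 fell by either adjustment, with Ccna2 at 2.55 ± 0.17 and Mcm2 at 2.57 ± 0.18 (camera adjusted p = 3.84e-13, and adjusted p = 0.157 with an estimated correlation). Of 21 cohesin genes 13 rose and 2, Stag3 and Rec8 (-0.82 ± 0.21), fell by either adjustment. Cdca5 (3.40 ± 0.25), the releasing factor Wapl (1.30 ± 0.14) and Stag1 (1.176 ± 0.14) were among the higher ones. Of 8 condensin genes 6 rose and 1 fell by either adjustment. The cohesin and condensin lists had camera adjusted p-values of 0.0227 and 0.0304, and adjusted p = 0.264 with an estimated correlation for both.

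Of 11 fetal male germ cell genes 3 rose and 7 fell by either adjustment (camera adjusted p = 0.0325). Piwil4 (-2.60 ± 0.13) and Ovol1 (-4.03 ± 0.52) fell with Dnmt3l, while Nanos3 (4.46 ± 0.46), an RNA-binding protein that spermatogonia also use, rose. Of 16 pluripotency genes 2 rose and 9 fell by either adjustment, with Dppa4 at -2.37 ± 0.14 and Pou5f1 at -1.60 ± 0.2 (camera adjusted p = 0.0227). Of 19 imprinted genes 2 rose and 10 fell by either adjustment, with Grb10 at -3.60 ± 0.18 and Kcnq1ot1 at 4.38 ± 0.45 (camera adjusted p = 0.0304). These 3 lists had adjusted p = 0.264 with an estimated correlation. Of 13 Hox genes 0 rose and 8 fell by either adjustment, with Hoxa4 at -5.01 ± 0.49 (camera adjusted p = 0.0481, and adjusted p = 0.462 with an estimated correlation). Of 91 oxidative phosphorylation genes 40 rose and 20 fell by either adjustment (camera adjusted p = 0.0227, and adjusted p = 0.72 with an estimated correlation). Lists that moved both ways without passing included the piRNA pathway (6 rose, 10 fell, camera adjusted p = 0.171, median 0.07 against a mean of -0.41), ribosomal protein genes (31 and 27, or 32 and 27 adjusted over the list alone, adjusted p = 0.147) and meiotic prophase (9 and 10, or 9 and 8 adjusted over the list alone, adjusted p = 0.489). With DESeq2 size factors the medians of the ribosomal list (0.02 to -0.01) and of the meiotic list (0.02 to -0.01) changed sign.

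**Figure D4:**
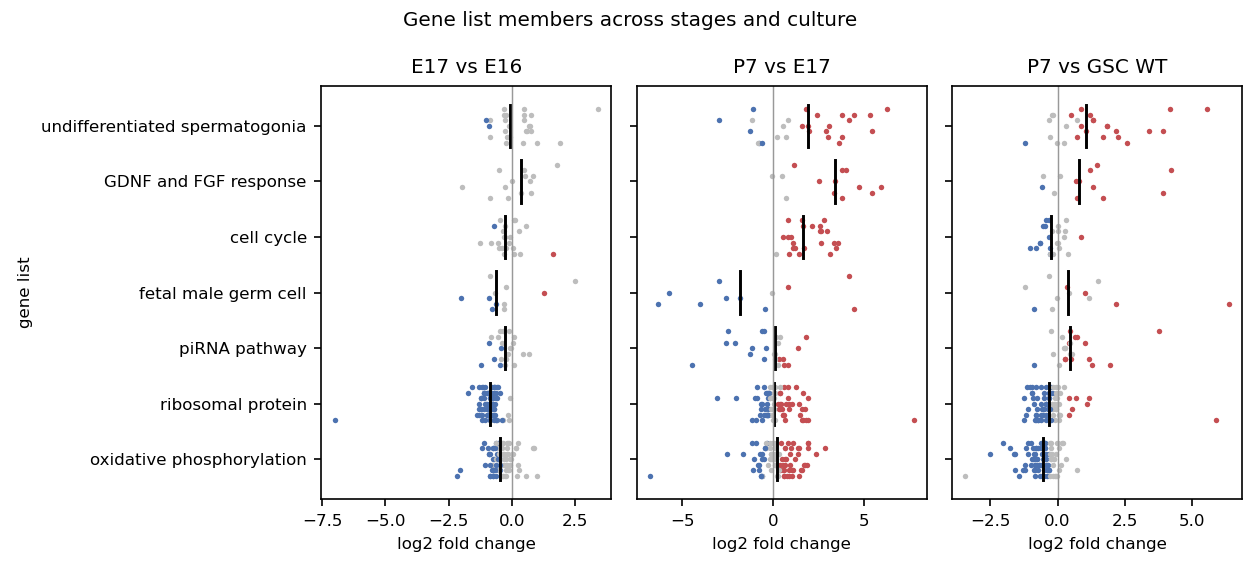
Log2 fold change (horizontal axis) of each tested member of 7 gene lists (vertical axis) in the comparisons E17 against E16, P7 against E17 and P7 against WT GSCs, with red and blue points for members past the threshold, grey points for the rest and a black line at the list median. The ribosomal protein median is -0.88 in the first comparison, and the GDNF and FGF median is 3.41 in the second.

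The lists of somatic cells were read next, and the first 4 did not pass. Of 4 peritubular myoid genes 4 fell, of 4 Leydig cell genes 3, of 6 endothelial genes 4 and of 11 Sertoli genes 4, with 0 rising in any of these lists by either adjustment (camera adjusted p = 0.05, 0.252, 0.252 and 0.489). Examples are Des (-4.28 ± 0.39), Cyp11a1 (-4.77 ± 0.61), Egfl7 (-1.86 ± 0.21) and Clu (-1.32 ± 0.23). Of 11 fibroblast and feeder genes 2 rose and 7 fell by either adjustment, with Postn at -3.64 ± 0.25 (camera adjusted p = 0.0227, and adjusted p = 0.342 with an estimated correlation). Levels summed over all listed genes, tested or not, at E17 and P7 were 111 and 16.7 RPM for myoid, 49.0 and 6.46 for Leydig, 165 and 52.1 for endothelial, 209 and 99.9 ± 30.6 for Sertoli and 674 and 396 for fibroblast and feeder genes. Of 12 Rhox genes 0 rose and 7 fell by either adjustment (camera adjusted p = 0.05), with a median of -2.43 that became -2.10 with members at 0 set to their bound.

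**Figure D5:**
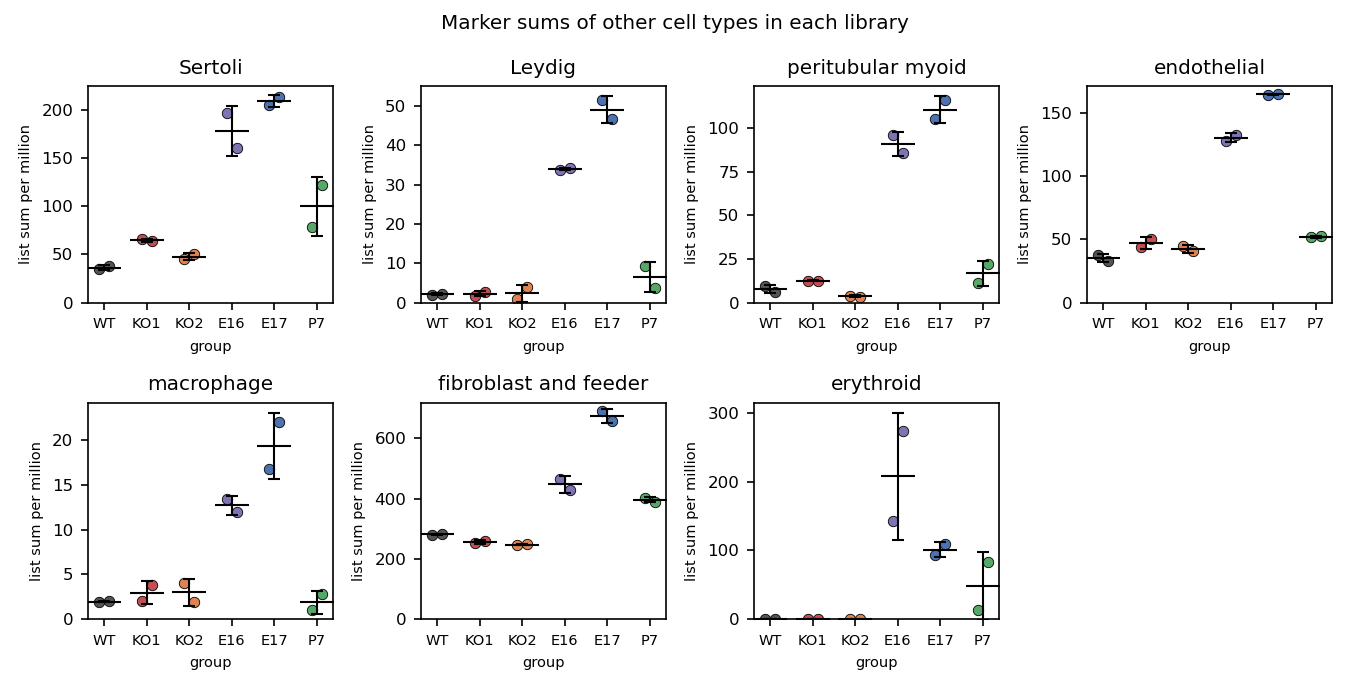
Summed RPM of marker genes for 7 other cell types in each library (points) with the group mean ± SD (bars, n = 2) over the 6 groups. Sertoli, Leydig, myoid, endothelial and fibroblast sums are higher in the E16 and E17 libraries than at P7, and the erythroid sum at P7 comes mainly from 1 library (47.5 ± 49.5).

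The genes with the largest rises from E17 to P7 had 0 counts at E17. Pabpn1, a poly(A)-binding protein gene, was at least 169.3-fold higher at 279.7 ± 2.63 RPM, and Adnp at least 127.4-fold, Ddi2 89.9-fold, Csnk2b 77.4-fold, Lbhd1 53.8-fold, Dync1li1 51.8-fold, Rbm4 48.9-fold, Cmtr1 47.0-fold, Fkbp2 34.8-fold and Scamp3 33.3-fold. Pabpn1 and Csnk2b are expressed in most cell types, and Pabpn1, Adnp, Lbhd1, Rbm4, Cmtr1, Fkbp2 and Scamp3 were also at 0 in all 10 libraries counted with the other list. Genes at 0 at P7 and at least 44.8-fold to 58.2-fold lower than at E17 were Itih2, Treml1, Cd22, R3hdml, Atp6v0a2, the zona pellucida gene Zp2, Tbx19, Cdhr1, Gucy2c and Ceacam10. Over 49 markers of tissues outside the testis the median was 6.17 RPM at E17 and 0.31 at P7. Whether the falls share a source with that signal was not tested. Of the 20 genes 9 overlap another gene. In all 10040 of 14776 genes changed, 4458 higher and 5582 lower (edgeR quasi-likelihood test). The count was 5387 of 7872 genes tested when overlapping genes were left out, and 6388 with a stricter filter on low counts.

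P7 germ cells were compared with WT GSCs to set cells in vivo against their cultured counterparts, and culture, line and gene list differ together here. Genes of undifferentiated spermatogonia were higher in vivo. Of 27 tested, 18 rose and 1 fell (19 and 1 adjusted over the list alone), with Lhx1, a target of GDNF, at 56.3 ± 11.3 against 3.41 ± 0.95 RPM (log2 fold change 3.91 ± 0.34, adjusted p = 1.18e-11, edgeR quasi-likelihood test, Benjamini-Hochberg). Tcl1 (2.26 ± 0.19) and the cadherin gene Cdh1 (3.39 ± 0.33) were higher, and T (brachyury) had 139 counts against 3, a ratio of 56.7 (95% counting interval 19.02 to 278.5). This list passed with the preset correlation (camera adjusted p = 9.66e-08) and also had adjusted p = 0.0176 with an estimated correlation, the only list call of any comparison that was kept there. Spermatogonial differentiation genes were mostly lower, with 2 of 9 higher and 6 lower by either adjustment, among them Rhox13 (-1.97 ± 0.16), Sohlh2 (-1.89 ± 0.16) and Stra8 (-1.34 ± 0.14), while Sohlh1 (1.42 ± 0.15) was higher (camera adjusted p = 0.00518, and adjusted p = 0.205 with an estimated correlation).

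Of 13 GDNF and FGF genes 9 rose and 1 fell by either adjustment (camera adjusted p = 0.00041), and of 23 piRNA genes 12 rose and 1 fell (14 and 1 adjusted over the list alone, camera adjusted p = 7.12e-05), with Tdrd9 at 3.75 ± 0.18 and Morc1 at 1.93 ± 0.13. Both had adjusted p = 0.0526 with an estimated correlation. Of 92 oxidative phosphorylation genes 0 rose and 66 fell (0 and 70 adjusted over the list alone), with a median of -0.54 (-0.53 with members at 0 set to their bound), Uqcrq at -1.42 and Cox6b1 at -1.21 (camera adjusted p = 1.83e-21, and adjusted p = 0.175 with an estimated correlation). Of 80 ribosomal protein genes 7 rose and 49 fell (7 and 52 adjusted over the list alone), with Rpl36 at -1.26 ± 0.1 (camera adjusted p = 2.32e-10, and adjusted p = 0.403 with an estimated correlation). Of 24 cell cycle genes 1 rose and 11 fell by either adjustment, with Top2a at -1.02 ± 0.1 and Cenpf at 0.88 ± 0.12 (camera adjusted p = 0.0222, and adjusted p = 0.272 with an estimated correlation). Of 22 Hox genes 0 rose and 8 fell by either adjustment, with Hoxb7 at -3.08 ± 0.27 (camera adjusted p = 0.00402, and adjusted p = 0.0967 with an estimated correlation), and their median of -0.81 became -0.40 with members at 0 set to their bound. Of 21 cohesin genes 4 rose and 5 fell by either adjustment, the meiotic members Smc1b (-1.29 ± 0.12), Rec8 (-1.42 ± 0.17) and Stag3 among the lower ones (camera adjusted p = 0.356).

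Of 11 Sertoli genes 8 rose and 1 fell (9 and 1 adjusted over the list alone), with Clu at 4.21 ± 0.36 (camera adjusted p = 0.00381, and adjusted p = 0.205 with an estimated correlation) and a median of 2.103 that became 1.72 with members at 0 set to their bound. Of 5 erythroid genes 4 rose and 0 fell by either adjustment (camera adjusted p = 0.0464, and adjusted p = 0.322 with an estimated correlation), with a median of 7.24 that became 3.02 in the same way. The globin Hbb-bs was at least 35.9-fold higher, at 8.22 and 47.9 RPM in the P7 libraries. The other tested lists of cell types did not pass. Of 6 endothelial genes 3 rose and 0 fell, of 12 fibroblast and feeder genes 2 rose and 2 fell, and of 4 Leydig and 4 peritubular myoid genes 0 changed, all by either adjustment (camera adjusted p = 0.175, 0.862, 0.4 and 0.528).

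Of the 10 genes with the largest rises, Pabpn1 was at least 357.6-fold higher, Adnp 269-fold, Lbhd1 113.6-fold, Rbm4 103.2-fold, Cmtr1 99.2-fold, Fkbp2 73.4-fold, Scamp3 70.2-fold, Rpp14 61.0-fold and Moap1 60.3-fold, each at 0 in WT GSCs, and Ddi2 had 931 counts against 1, a ratio of 1140 (95% counting interval 204.1 to 45080). Among the falls, Atp6v0a2 was at 0 at P7 and at least 29.6-fold lower, and Mia2, Tnfrsf13b and Gbp2b had ratios of 282.5 (interval 50.4 to 11190), 121.3 (33.3 to 1006) and 98.0 (26.8 to 813.8). Atp6v0a2, Mia2 and Tnfrsf13b are among 7 genes at 10 RPM or more in all 10 libraries of the other list and under 1 RPM in both P7 libraries. The histone variant gene H2afz went from 1211 ± 37.2 in WT GSCs to 26.6 ± 0.86 RPM at P7 (-5.64 ± 0.13), and Fam90a1b (-5.34), Sinhcaf (-4.21), the caveolar gene Cavin1 (-3.60), S100a6 (-3.55) and Hoxb13 (-3.46) were lower too. Of these 20 genes 12 overlap another gene. In all 4909 of 15827 genes differed, 2538 higher at P7 and 2371 lower (edgeR quasi-likelihood test). The count was 3200 without P7 replicate 1, 2612 when overlapping genes were left out and 2426 with an added log2 threshold of 1.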

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

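The tests of feeder cells, of a shared culture state, of sequencing depth and of signal spread over all genes were chosen only after the result was seen.

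In total 99 genes differed between the KO1 and KO2 lines by the test of the difference itself (edgeR quasi-likelihood test). The named ones higher in KO1 were Tktl1 (log2 difference 6.86), Magea8 (1.88), Dmrtc2 (1.58), Magea5 (1.44), Tex12 (1.43), H19 (1.39), Kit (1.25), Morc1 (1.25), Kdm5c (1.16) and Stag3 (1.05). Those higher in KO2 were Myof (-1.49), Nid1 (-1.22), Atp2b4 (-0.97), Ikbkb (-0.95), Gba2 (-0.89), Pou2f2 (-0.88), Afp (-0.86), Tctn2 (-0.86), LOC108167440 (-0.84) and Zfp704 (-0.79). The count was 189 and 185 without WT replicate 1 or 2, 43 and 41 without KO1 replicate 1 or 2, and 45 and 42 without KO2 replicate 1 or 2.

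Poly(A) sequences of transgenes, outside the gene tests, held signal above the limit that a count of 0 allows. The one named RBG had 271.5 RPM in WT GSCs, 106.4 in KO1 and 58.04 in KO2, and 0 counts in the in vivo libraries. The one named EF1a had 41.7 in WT GSCs, 22.3 in KO1, 24.8 in KO2, 22.9 at E16, 17.1 at E17 and 44.6 at P7. The one named BGH had 24.4 at E16, 21.9 at E17 and 38.1 at P7. The one named SV40 had 5.63 at E16, where all 32 counts came from replicate 2.

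A first pattern is a set of genes near 0 in all GSC, E16 and E17 libraries and well expressed at P7. Of 8852 genes at 10 RPM or more in both P7 libraries, 30 were under 1 RPM in all 10 other libraries. Of the 29 with coordinates 18 (62.1%) overlap a gene that only the other list holds, against 1040 of 8817 other genes (11.8%, odds ratio 12.24, two-sided Fisher's exact test p = 2.08e-10). For these 18, Adnp among them, reads on shared sequence may therefore have gone to other gene models or been set aside as ambiguous with that list, which leaves the others, such as Pabpn1 with 0 such overlaps, without a tested explanation. The set was chosen to be near 0 in the cultured GSC libraries as well as the fetal ones. Those levels therefore cannot decide whether stage plays a part. Of the 30 genes 23 had 0 counts in all 10 other libraries. For a single gene stage, culture and list cannot be separated here because both P7 libraries use the same list. In the other direction 7 genes, Atp6v0a2 among them, were at 10 RPM or more in all 10 other libraries and under 1 RPM in both P7 libraries. The overlap test was not made for these 7.

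A second pattern is the rise of the GDNF and FGF list and the fall of the piRNA list in both Stag3 knockout lines. Fewer feeder cells in the knockout cultures, if feeders were used, stay possible, since the fibroblast and feeder list had a median log2 fold change of -0.851 with 5 of 9 members called lower and 4 not past the threshold. The summed level of all 12 listed genes moved less, from 281 RPM in WT to 256 in KO1 and 247 in KO2. Scaling of the libraries is argued against by the calls with ERCC totals, where in the mean of both lines at least 87.5% of the GDNF and FGF members called higher and of the piRNA members called lower were also called, as were 8 of 8 and 10 of 10 in KO1 and 9 of 9 and 12 of 16 in KO2. A culture state that both knockout lines share apart from Stag3 could give the same values, since the lines correlate at 0.766 across genes and the libraries include no other WT line and no rescue. Neither can be told apart from an effect of the genotype, which stays open.

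The last pattern is the larger number of genes detected in fetal libraries. At an equal depth of 1500000 counts the mean was 14351 genes in WT GSCs, 18731 at E16, 20824 at E17 and 16052.5 at P7, so that E17 held 1.45 times the WT number, which depth does not account for. Signal falling on all genes alike, such as genomic DNA, is argued against by 4119 protein-coding genes with no GSC count, which averaged 2.28 RPM at E17 against 0.0525 for 1420 receptor genes, a ratio of 43.3. Somatic cells of the testis alone are argued against by 49 markers of other tissues, whose median of 6.17 was 0.9 times the median of 55 testis somatic markers (6.9). Priming inside transcripts, reads from other libraries and a broad transcription of fetal germ cells were not tested and may each still apply.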

How the results depend on the processing

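The alternatives with ERCC totals as size factors, without mitochondrial genes, without overlapping genes and without genes near 0 with 1 gene list were chosen only after the result was seen. Of the main results 294 values kept their direction and side of the threshold (counts within 1.5 times), and 68 counts moved and 2 values lost their call. The numbers of changed genes are given here in the order mean of both lines, KO1, KO2, KO1 against KO2, and both lines. They were 1421, 858, 1008, 39 and 545 with all 12 libraries in a fit, 566, 514, 564, 50 and 320 with an added log2 threshold of 1, and 1083, 679, 864, 35 and 461 by the DESeq2 Wald test. With ERCC totals they were 1447 for the mean, 1191 for KO2 and 595 for both lines. E17 against E16 gave 1763 with all 12 libraries and 335 with the log2 threshold. P7 against E17 gave 6388 with the stricter filter and 5387 without overlapping genes, and P7 against GSC WT gave 2426 with the log2 threshold and 2612 without overlapping genes. The log2 threshold and the filters lower counts by their construction, as does testing fewer genes, and for the rest the cause was not tested.

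With 1 library left out there were 1705 to 2170 genes for the mean of both lines, 859 to 1779 for KO1, 905 to 1869 for KO2, 41 to 189 for KO1 against KO2, 605 to 1171 for both lines, 232 to 3645 for E17 against E16, 8120 to 12078 for P7 against E17 and 3200 to 6044 for P7 against GSC WT. The KO1 count was 875 and 859 without its replicate 1 or 2, the KO2 count 977 and 905, and for E17 against E16 it was 3645 and 1506 without E16 replicate 1 or 2 and 232 and 260 without E17 replicate 1 or 2. The P7 against GSC WT count was 3200 without P7 replicate 1. An arm left with 1 library was assumed to vary like the other groups. Of the 20 named genes of KO1 against KO2, 12 kept their call with all 12 libraries, 12 with the log2 threshold, 9 by DESeq2 and 11 to 20 with a library left out. For E17 against E16 it was 11 by DESeq2 and 11 to 20 with a library left out. For P7 against E17 it was 11 without overlapping genes and 10 without genes near 0 with 1 list, and for P7 against GSC WT 8 and 8. The cause was not tested where genes were not removed.

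Stag3 kept its direction and call in the knockout comparisons, with ranges of -1.05 to -0.92 for the mean, -0.58 to -0.45 for KO1 and -1.61 to -1.46 for KO2, except that -0.478 in KO1 and -0.940 at P7 against GSC WT lie inside the log2 threshold of 1. With an estimated correlation camera called 0 lists in 6 comparisons and 1 at P7 against GSC WT, with 2 to 5 lists per comparison at an unadjusted p under 0.05. With fry 9 lists were called for the mean of both lines, 8 for KO1, 9 for KO2 and 1 for KO1 against KO2. In the mean of both lines the GDNF and FGF list and the piRNA list each had adjusted p = 0.00774 by fry. The ribosomal protein list (fry adjusted p = 0.138) and the mitochondrial list (fry adjusted p = 0.205) were not called there. Fry called 4 lists for E17 against E16, 20 for P7 against E17 and 21 for P7 against GSC WT. The p53 targets at P7 against E17 reversed to a direction of -1 (adjusted p = 0.0213 by fry, not significant in camera). Fry does not compare a list with other genes. Among single genes and lists 177 values were weaker, 26 stronger and 1 reversed. Replicate numbers do not pair the samples, as deviations of equal numbers correlated at -0.052 to 0.043, and a replicate block gave 3 lists for E17 against E16 and kept 2284, 1621, 1860, 99, 970, 9894 and 4794 of the calls of the 7 comparisons. Depth limits the lowest level seen, with a floor of 1.06 to 1.73 RPM in fetal against 0.75 to 1.05 in GSC libraries. For E17 against E16 7.5% of genes changed 1.5-fold were called in the simulated data, against 50.7% for the mean of both knockout lines and 41.8% for KO1 against WT. The simulation took gene levels, spread, depth and group sizes from the data, so the difference comes from these. They were not varied singly.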

Other observations

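The values for neighbouring pairs in E17 against E16 and P7 against GSC WT, and the genes named first here, were chosen only after the result was seen.

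Among the genes called lower in both Stag3 knockout lines, 4 that were chosen after their values were seen had 0 counts in all 4 knockout libraries. They were Xlr5c (12.2 ± 0.4 RPM in WT), Gm33302 (23.7 ± 3.12), Gm38425 (11.04 ± 4.83) and Trim52 (3.53 ± 0.41). The same genes stood at 54.7 ± 0.82, 48.3 ± 6.45, 37.0 ± 2.52 and 21.6 ± 3.88 RPM at P7.

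Markers of tissues outside the testis were seen in the fetal libraries, with list medians at E17 of 28.8 RPM for skeletal muscle, 8.4 for neurons, 8.01 for B cells, 3.85 for intestine, 3.29 for liver and 1.94 for lung. Over all 49 of these markers the median was 0.12 in WT GSCs and 0.31 at P7. The share of all counts taken by ERCC spike-ins was 1.37% ± 0.22 at E16, 0.213% ± 0.026 at E17 and 5.27% ± 0.82 at P7, against 3.01% in WT, 3.32% in KO1 and 2.97% in KO2. ERCC totals were tried as size factors only in the fit of the GSC libraries. Fold changes that involve in vivo libraries are therefore relative to the other genes.

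It was asked whether genes that fell in both knockout lines are transcripts that fetal germ cells hold at a higher level. Of 557 such genes that were also tested in vivo 136 (24.4%) were lower at P7 than at E17, against 114 of 452 genes (25.2%) that rose in both lines. The odds ratio was 0.96 (95% interval 0.72 to 1.28, two-sided Fisher's exact test p = 0.77), and the interval lies under an odds ratio of 1.5.

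It was also asked whether genes that changed in both lines lie next to each other. Of 10581 neighbouring pairs that do not overlap, 74 were called in the same direction, against a mean of 40.1 and a highest value of 66 in 10000 shuffles of gene order (ratio 1.84, permutation p = 0.0001, the smallest the shuffles can give). This is consistent with domains of neighbouring genes that change together, and duplicated genes with shared reads or shared regulation may give the same value. The ratio was 1.35 for P7 against GSC WT (915 against 678 pairs) and 0.78 for E17 against E16 (28 against 36.1).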
